A study of Mus musculus with 12 samples.

How the data were processed

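Total RNA was measured in hematopoietic stem cells sorted from mouse bone marrow, in 12 libraries from 4 genotypes with 3 libraries each. The genotypes, taken from the sample labels, were wild type, NrasG12D/+, Tet2+/- and the compound mutant that carries both alleles. The single deposited table holds log2 RPKM (reads scaled to gene length and library size), an other unit than counts, for 18546 genes named by symbol. Per the labels, the authors used CASAVA 1.8.2, TopHat2 and edgeR with the mm10 genome build, with no role or order stated for each tool. The deposited values fitted whole read counts with a prior of 0.25 reads, to a tolerance of 0.001 reads, for every gene. Those recovered reads gave the depth of each library, 19205045 to 36890942 reads in genes. Counts of 0 were bounded by a floor of 3 reads per library, which covers counting error only because reads without molecular identifiers are not independent molecules.

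Genes with at least 1 RPKM in at least 3 libraries were tested, which kept 15478 genes and left out 3068. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 as 1 mean per genotype over all 12 libraries, with 8 residual degrees of freedom and a variance trend. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and all tests were two-sided. There were 6 planned comparisons: each mutant genotype against wild type, the compound mutant against each single mutant, and the interaction (compound minus Nras minus Tet2 plus wild type). The 3 comparisons with wild type share the same 3 wild-type libraries. A further pair of comparisons, each allele averaged over the genotypes of the other, was added after the data were seen. The same holds for intervals at the 95% level and for values of sorting markers and of short lists. An exact permutation test of each list's level (the median over members of the log2 value relative to the gene's mean), 6 carriers of an allele against 6 other libraries, was also added then. Its 924 arrangements allow a smallest p of 0.00216, while an exact test of 3 against 3 cannot go below 0.1. Exchanging labels only within replicate numbers, a later addition, gives 216 arrangements and a smallest p of 0.00926. Group values are mean RPKM ± SD with n = 3, and log2 differences are given ± SE.

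Before the data were examined, 33 gene lists with 729 members were fixed from general knowledge, of which 641 were in the table. They were HSC identity, quiescence, G2/M proliferation, S phase, MAPK output and feedback, immediate early genes, STAT5 targets, cytokine receptors, interferon response, NF-kB and inflammation, and antigen presentation. Lineage lists covered lympho-primed progenitors, granulocyte-monocyte progenitors, mature granulocytes, monocytes and macrophages, erythroid cells, megakaryocytes, B lineage, T and NK lineage, mast cells with basophils and eosinophils, and stroma and endothelium. The others were DNA methylation machinery, Ras pathway components, the Hox cluster and leukemic self-renewal, oxidative phosphorylation, glycolysis, cholesterol synthesis, p53 targets, the unfolded protein and integrated stress response, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. The 28 lists with at least 5 tested members entered limma's camera test with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each call was repeated with an inter-gene correlation estimated from the data.

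Genes were named by a rule fixed at the same time. It took the 2 targeted genes, then the 8 highest and 8 lowest log2 differences among genes past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, genes with the smallest unadjusted p and no overlap filled the count to 5 and are given as values that did not pass. In each list discussed, the rule named 2 to 4 members with the smallest p, though for some lists fewer or other members are given. Names made of Gm and digits, ending in Rik, or beginning with Mir, Snor, AK, BC, LOC or AI and digits were left out of naming, while other clone-based names, such as RP23-370D2.2, were not. 1600002K03Rik and Gm15371 fall outside the rule and were chosen after their values were seen. Coordinates came from GENCODE M21, in which 17737 symbols matched 1 gene.

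The settings varied from the start were no minimum on RPKM, log2(RPKM + 0.5), median-centred libraries, quantile normalization, only the 2 groups compared, a replicate block, library quality weights, no variance trend, the estimated inter-gene correlation and each library left out in turn. Added after the data were seen were voom on the recovered reads, sex as a covariate, and a fit without wild-type replicate 1 and Nras replicate 2, the 2 libraries with the most genes at 0 reads. Sex was read from Xist and Y-linked genes. The method was tested on simulated values drawn from each gene's mean and spread in the libraries, independently between genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.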

Results

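Hematopoietic stem cells (HSCs) of the SLAM gate, which are lineage-negative, Sca1-positive and cKit-positive cells with CD150 and without CD48, came from the bone marrow of C57BL/6 mice aged 10 to 12 weeks. Total RNA depleted of ribosomal and mitochondrial RNA was sequenced in 3 libraries each of wild type, NrasG12D/+ (an activated Ras GTPase), Tet2+/- (loss of 1 copy of a DNA demethylation enzyme) and the compound mutant. Reads in genes were 19205045, 25247216 and 34631653 in wild type and 29789868, 28750542 and 36890942 in Nras mutants. They were 34533120, 26376902 and 26783004 in Tet2 mutants and 20935368, 33941484 and 29076083 in compound mutants. Between 12613 and 14111 genes per library reached 1 RPKM. Wild-type replicate 1 had 3824 genes at 0 reads and Nras replicate 2 had 3268, the most of the 12, while wild-type replicate 2 had the fewest, 1000. Each group held both sexes, with 1 male library in all groups but Tet2+/-, which had 2. All libraries numbered 1 were male and all numbered 2 female, and of those numbered 3 only Tet2 replicate 3 was male. Sex and replicate number thus largely coincide, so adjusting for sex and blocking by number are not independent checks. Between pairs of replicates of the same genotype the mean chi-square was 46.1 to 120 times that of counting error, over genes with at least 20 reads in the pair. This mean is weighted to abundant genes and, in pairs of unlike sex, includes sex-linked genes.

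**Figure D1:**
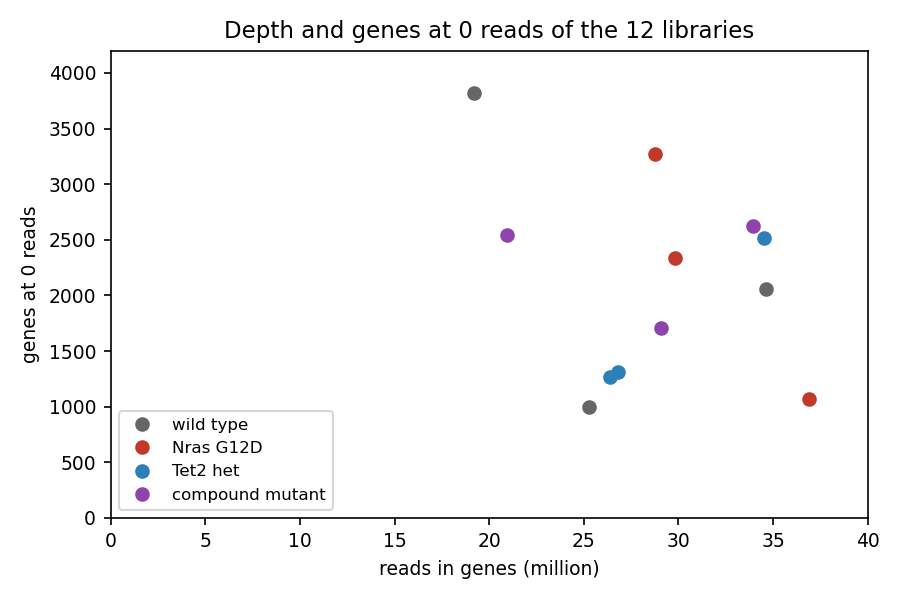
Reads in genes and number of genes at 0 reads for each of the 12 libraries, by genotype. Depth runs from 19205045 to 36890942 reads, and genes at 0 reads from 1000 to 3824.

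The targeted genes were read first. Nras (ENSMUSG00000027852, mm10 chromosome 3, 103058285 to 103067914) stood at 5.58 ± 0.597 RPKM in wild type, 5.74 ± 0.882 in Nras mutants, 6.08 ± 0.778 in Tet2 mutants and 6.24 ± 0.981 in compound mutants (SD, n = 3). The log2 difference from wild type was 0.03 in Nras mutants (95% interval -0.41 to 0.48) and 0.15 in compound mutants (-0.29 to 0.60), with adjusted p of 0.999 and 0.894. Tet2 (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139) stood at 4.95 ± 0.0301, 5.71 ± 1.16, 4.72 ± 0.579 and 4.98 ± 0.615 RPKM in the same order. Its log2 difference from wild type was -0.08 in Tet2 mutants (-0.52 to 0.37) and 0.00 in compound mutants (-0.44 to 0.44), neither past the threshold. With the Tet2 allele averaged over Nras genotypes the difference was -0.13 (-0.44 to 0.18). These intervals for Tet2 lie above -1, the log2 value of losing the RNA of 1 of 2 copies, so the data go against such a loss of Tet2 RNA. Values over whole genes do not show which allele was transcribed, so they are no check of the genotypes.

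Nras mutants were compared with wild type to ask what the activated Ras allele alone changes in HSCs. Proliferation genes were higher in Nras mutants: Kif11, a mitotic kinesin, stood at 34.3 ± 4.71 RPKM against 16.6 ± 1.89 in wild type (SD, n = 3), and Top2a, the topoisomerase that untangles chromosomes, at 39.0 ± 6.44 against 22.8 ± 2.18. The G2/M proliferation list rose, with 25 of 26 members positive and a median log2 difference of 0.53 (adjusted p = 4.95e-10, and adjusted p = 0.186 with an estimated correlation). Kif11 (log2 1.05 ± 0.17 SE), Top2a (0.76 ± 0.13), Mki67, the Ki-67 antigen (0.83 ± 0.18), and Cdk1, the mitotic kinase (1.04 ± 0.27), were the 4 members that rose adjusted over the list alone, against 0 adjusted over all genes. Genes induced by Ras signaling through ERK rose as a list, with 10 of 16 positive and a median of 0.41 (adjusted p = 0.00368, and adjusted p = 0.314 with an estimated correlation). Its 4 members that rose adjusted over the list alone (0 over all genes) were Dusp4 and Dusp6, phosphatases that switch ERK off, Ccnd1, a D-type cyclin, and Etv5, an ETS transcription factor. Dusp6 stood at 28.9 ± 8.08 RPKM against 16.1 ± 1.04, Dusp4 at 14.4 ± 2.65 against 4.22 ± 3.00, Ccnd1 at 23.6 ± 4.21 against 11.7 ± 2.63 and Etv5 at 8.26 ± 1.24 against 3.40 ± 1.73. Dusp4 also stood above wild type in Tet2 mutants, at 10.5 ± 1.90 RPKM, without passing there (limma, adjusted p = 0.137 over the list alone). Dusp6, Ccnd1 and Etv5 stood at 17.1 ± 4.20, 13.3 ± 5.83 and 4.21 ± 1.53 RPKM in Tet2 mutants. Replication-dependent histones rose, with 16 of 22 positive and a median of 0.48 (adjusted p = 8.16e-05, and adjusted p = 0.506 with an estimated correlation). Of these, 7 rose adjusted over the list alone and 0 over all genes, among them Hist1h4h (10.7 ± 1.14 to 27.0 ± 5.89 RPKM), Hist1h1b (42.5 ± 1.61 to 74.3 ± 26.0), Hist1h2ab and Hist1h1d. The S phase list rose, with 23 of 25 positive and a median of 0.31 (adjusted p = 0.000299, and adjusted p = 0.499 with an estimated correlation), while 0 members passed singly by either adjustment. Chaf1a, a chromatin assembly factor, stood at 29.7 ± 4.11 against 19.8 ± 0.897 RPKM, Pola1, a DNA polymerase, at 15.2 ± 0.781 against 12.0 ± 1.39, and Mcm2, a replication helicase subunit, at 67.9 ± 9.24 against 52.2 ± 8.12.

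Among single genes in that comparison, 1600002K03Rik, a gene without a known function on chromosome 10 (80172944 to 80175146), was the 1 gene that rose over all 15478 tested and 0 fell (adjusted p = 0.000651). It had 0 reads in the 3 wild-type libraries and 107 to 149 in Nras mutants, at least 33.5-fold higher. Other genes with small p did not pass. Gem, a small GTP-binding protein of the RGK family, stood at 37.7 ± 15.2 against 5.88 ± 1.12 RPKM (log2 2.63 ± 0.33 SE, adjusted p = 0.0746). Slc22a3, an organic cation transporter, stood at 38.2 ± 2.73 against 19.0 ± 1.67, H1f0, a linker histone, at 68.0 ± 12.3 against 35.0 ± 6.64 and Robo3, a Robo family receptor, at 1.98 ± 0.634 against 0.139 ± 0.0606. A lower value was that of Gda, guanine deaminase, at 2.63 ± 1.14 against 10.4 ± 2.66 RPKM. Plxdc2 stood at 7.45 ± 0.598 against 13.7 ± 2.32, Asrgl1 at 7.13 ± 1.09 against 14.1 ± 3.38 and RP23-370D2.2 at 0.420 ± 0.688 against 8.95 ± 4.65. These genes, Kif11 included, had adjusted p between 0.221 and 0.578. In the Hox list, Hoxa4 stood at 2.48 ± 0.965 against 8.52 ± 3.56 RPKM and was the 1 of 19 members that fell adjusted over the list alone, with 0 over all genes. Hoxa4 was also below wild type in Tet2 mutants (4.95 ± 0.997 RPKM) and compound mutants (4.41 ± 1.12). Unadjusted p was under 0.05 for 868 genes, where chance gives 774. Groups did not overlap for 9.7% of genes, where chance gives 10%. The call of 1600002K03Rik was lost with quantile normalization (adjusted p = 0.400), with only the 2 groups in the fit (0.255) and with voom (0.312), within a range of 0.000197 to 0.400 over all alternatives. The gene count was 18 without wild-type replicate 2 or Nras replicate 3, 3 without wild-type replicate 1, and 2 without wild-type replicate 3, Tet2 replicate 1 or compound replicates 2 or 3. The S phase call was lost without wild-type replicate 2 (0.364), the histone call without it (0.138) or Nras replicate 3 (0.0884) and the MAPK call without the 2 libraries with most genes at 0 reads (0.0682). Then 2 lists passed without wild-type replicate 2 and 8 without Nras replicate 2.

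Tet2 mutants were compared with wild type for the effect of losing 1 Tet2 copy. Of G2/M genes that were high in Nras mutants, Kif11 stood at 20.9 ± 1.5 against 16.6 ± 1.89 RPKM, Mki67 at 75.4 ± 7.86 against 77.0 ± 19.5 and Ccnb2, a B-type cyclin with the smallest p of the list, at 8.17 ± 4.42 against 16 ± 8.17 (SD, n = 3). None of the 3 passed. Of the other genes with the smallest p, Rwdd2b stood at 7.93 ± 0.585 against 3.67 ± 0.738 and Tmed4, a cargo receptor of the secretory pathway, at 18.2 ± 1.25 against 10.5 ± 2.44. Tvp23b stood at 8.84 ± 0.643 against 4.85 ± 0.455. Tmem147 stood at 10.0 ± 3.36 against 22.1 ± 4.2 RPKM, Msra, which repairs oxidised methionine, at 6.78 ± 1.01 against 15.1 ± 3.81, and Sertad1, a regulator of cyclin-dependent kinases, at 3.23 ± 0.595 against 7.37 ± 0.441. Cxxc1, a subunit of the histone methyltransferase complex that binds CpG islands, stood at 31.0 ± 0.669 against 46.5 ± 9.16 and RP24-137F10.1 at 39.6 ± 4.19 against 68.6 ± 10.6. The microRNA mmu-mir-7682 had 0 reads in wild type and had 2 to 174 in Tet2 mutants, so that 1 library lay below the floor of 3 reads while the mean was at least 18.1-fold higher. AC092711.4 also had 0 in wild type and was at least 18.2-fold higher with 18 to 133 reads. None of these 10 genes passed (adjusted p = 1). 1600002K03Rik was again the 1 gene that rose and 0 fell, at least 19.1-fold higher with 21 to 125 reads (adjusted p = 0.00215).

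No list passed in Tet2 mutants, and the smallest adjusted p of the 28 was 0.0749, shared by antigen presentation (median log2 -0.15), ribosomal proteins (-0.11) and mitochondrially encoded genes (0.31, with 13 of 13 positive). With quantile normalization or voom 1 list passed, with the replicate block 3 and with sex as a covariate 4. Members with the smallest p were H2-Ab1, an MHC class II chain, at 10.9 ± 1.47 against 19.8 ± 4.04 RPKM, Tap2, a peptide transporter, at 17.2 ± 3.82 against 22.3 ± 2.72. Of ribosomal proteins, Rpl19 stood at 17 ± 3.11 against 24.4 ± 5.52. Of mitochondrially encoded genes, mt-Nd2 stood at 95 ± 20.6 against 64.9 ± 32.7 and mt-Nd5, also a subunit of respiratory complex I, at 254 ± 45.3 against 191 ± 34.0. The G2/M list had a median of -0.23 (adjusted p = 0.0767). In the quiescence list Txnip, a brake on glucose uptake, stood at 160 ± 26.9 against 110 ± 11.5 RPKM. In the S phase list Ccne2, an E-type cyclin, stood at 0.738 ± 0.05 against 1.75 ± 0.323. Neither passed adjusted over the list alone (0.134 and 0.235). Unadjusted p was under 0.05 for 519 genes, and groups did not overlap for 9.3% of genes, where chance gives 10%. The call of 1600002K03Rik was lost with log2(RPKM + 0.5) (adjusted p = 0.207), quantile normalization (0.999), only the 2 groups in the fit (0.916) and voom (0.972), within a range of 0.000591 to 0.999. The gene count was 20 without wild-type replicate 2 and 2 without wild-type replicate 1 or compound replicate 3, and 6 lists passed without wild-type replicate 2 or Tet2 replicate 1 and 2 without wild-type replicate 3 or Tet2 replicate 2.

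The compound mutant was compared with wild type for the effect of the 2 alleles together. Proliferation genes were again high: Mki67 stood at 153 ± 19.3 against 77.0 ± 19.5 RPKM, Top2a at 41.7 ± 3.48 against 22.8 ± 2.18 and Hmmr, a spindle protein, at 12.1 ± 2.62 against 6.62 ± 0.335 (SD, n = 3). The G2/M list rose, with 24 of 26 positive and a median log2 difference of 0.55 (adjusted p = 2.35e-08, and adjusted p = 0.297 with an estimated correlation). Top2a (log2 0.87 ± 0.13 SE), Kif11 (0.98 ± 0.17), Mki67 (1.02 ± 0.18) and Hmmr (0.84 ± 0.21) were among the 5 members that rose adjusted over the list alone, against 0 over all genes. Histones rose, with 17 of 22 positive and a median of 0.34 (adjusted p = 0.0102, and adjusted p = 0.650 with an estimated correlation), and 0 members passed by either adjustment. Of these, Hist1h1a stood at 124 ± 16 against 68.3 ± 36.8 RPKM, Hist1h2ac at 33.0 ± 1.77 against 19.1 ± 2.53 and Hist1h1c at 185 ± 24.7 against 125 ± 11.9. The unfolded protein and integrated stress response list fell, with 15 of 18 negative and a median of -0.31 (adjusted p = 0.00372, and adjusted p = 0.601 with an estimated correlation), and 0 members passed by either adjustment. Its lowest p were Asns, asparagine synthetase, at 1.24 ± 0.284 against 2.57 ± 0.452 RPKM, Trib3, a pseudokinase of the stress response, at 1.59 ± 2.35 against 3.42 ± 1.12. Xbp1, a transcription factor of the unfolded protein response, stood at 9.74 ± 2.41 against 15.9 ± 4.01. Glycolysis genes fell as a list, with 12 of 16 negative and a median of -0.19 (adjusted p = 0.0269, and adjusted p = 0.310 with an estimated correlation), and 0 members passed by either adjustment. Aldoa, aldolase, stood at 12.0 ± 0.689 against 15.8 ± 1.34 RPKM and Gpi1, glucose phosphate isomerase, at 24.8 ± 0.659 against 30.1 ± 2.38. MAPK output had a median of 0.15 and did not pass as a list (adjusted p = 0.0754). Its members Dusp6 (31.6 ± 5.67 against 16.1 ± 1.04) and Dusp4 (13.2 ± 1.07 against 4.22 ± 3.00) were 2 that rose adjusted over the list alone, with 0 over all genes. In Tet2 mutants Dusp6 stood at 17.1 ± 4.20 and Dusp4 at 10.5 ± 1.90 RPKM, so most of the Dusp4 difference was seen without the Nras allele.

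Among single genes in compound mutants, 1600002K03Rik was the 1 that rose and 0 fell, at least 20.4-fold higher than in wild type (adjusted p = 0.00142). Gem stood at 37.6 ± 9.26 against 5.88 ± 1.12 RPKM (log2 2.66 ± 0.33 SE, adjusted p = 0.0672). Slc22a3 stood at 39.9 ± 7.79 against 19.0 ± 1.67, Robo3 at 3.27 ± 0.221 against 0.139 ± 0.0606 and Kif11 at 33.2 ± 8.24 against 16.6 ± 1.89, and none of these passed. Csf2rb, the beta chain shared by several cytokine receptors, stood at 6.18 ± 0.874 against 13.6 ± 2.31 RPKM, with an adjusted p of 0.388 over all genes and 0.00606 over the cytokine receptor list alone. Fut8, which adds core fucose to glycoproteins, stood at 18.2 ± 2.44 against 37.0 ± 6.99. Prkd1, protein kinase D, the pseudogene Xlr4d-ps and Calr3, a testis calreticulin, had 0 reads in compound mutants and were at least 40.5-fold, 7.43-fold and 38.6-fold lower than in wild type, with adjusted p of 0.22, 0.22 and 0.413. Unadjusted p was under 0.05 for 994 genes, and groups did not overlap for 11.2% of genes, where chance gives 10%. The call of 1600002K03Rik was lost with log2(RPKM + 0.5) (0.0939), quantile normalization (0.391), only the 2 groups in the fit (0.571) and voom (0.520), within a range of 0.000403 to 0.571. The gene count was 17 without wild-type replicate 2, 6 without compound replicate 3, 4 without Nras replicate 2, 3 without wild-type replicate 3 or Nras replicate 1, and 2 without wild-type replicate 1, Nras replicate 3, Tet2 replicate 3 or compound replicate 1. The histone call was lost without wild-type replicate 2 (0.541) or compound replicate 2 (0.110). The glycolysis call was lost with quality weights (0.0511), no variance trend (0.0678), the 2 libraries left out (0.117), or without wild-type replicate 1 (0.102) or compound replicates 1 (0.0743) or 3 (0.0555). Then 7, 7 and 8 lists passed without wild-type replicate 1, Tet2 replicate 2 and compound replicate 2.

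The compound mutant was compared with Nras mutants for what Tet2 loss adds to the Nras allele. Of G2/M genes, Mki67 stood at 153 ± 19.3 and 134 ± 6.34 RPKM, Top2a at 41.7 ± 3.48 and 39.0 ± 6.44, Ccnb2 at 18.3 ± 3.87 and 27.0 ± 3.87 and Ube2c, a ubiquitin-conjugating enzyme, at 0.507 ± 0.873 and 1.81 ± 0.981 in compound and Nras mutants (SD, n = 3). None of them passed, and the list had a median of -0.02 (adjusted p = 0.914). Gem, which is not in that list, stood at 37.6 ± 9.26 and 37.7 ± 15.2. The interval of the log2 difference was -0.19 to 0.40 for Top2a and -0.69 to 0.76 for Gem. Higher values in compound mutants were Gbp2b, an interferon-induced GTPase, at 14 ± 3.90 against 1.36 ± 0.305 RPKM, and RP23-370D2.2 at 8.64 ± 2.87 against 0.420 ± 0.688. Tnrc6a, a partner of Argonaute in microRNA silencing, stood at 39.0 ± 7.22 against 25.1 ± 4.10, Brms1 at 26.7 ± 3.25 against 15.2 ± 4.05, and Cdk7, a kinase of the transcription machinery, at 7.86 ± 1.67 against 4.52 ± 0.610. Lower values were Rtca, an RNA cyclase, at 1.91 ± 0.198 against 4.74 ± 0.379 and Adat1, a tRNA deaminase, at 2.49 ± 0.410 against 5.05 ± 0.411. With 0 reads in compound mutants, Prkd1 was at least 17.5-fold and Xlr4d-ps at least 6.01-fold lower by the mean, with 2 to 41 reads in Nras mutants. Adjusted p for these genes lay between 0.682 and 1. By limma 0 genes changed, with 625 at an unadjusted p under 0.05 and 0 by voom, and groups did not overlap for 8.5% of genes, where chance gives 10%. Genes did pass in other settings. These were Gm22516 and Gm24610 with only the 2 groups in the fit, and Gm15371, Gm24378 and Prkd1 with no variance trend. Gm24610 also passed without the 2 libraries with most genes at 0 reads. No list passed (smallest adjusted p = 0.358, and 0 lists by voom), and the 1 member that fell adjusted over a list alone was Gpi1 in glycolysis, at 24.8 ± 0.659 against 31.9 ± 1.55 RPKM (0.0361), with 0 over all genes. As lists, mitochondrially encoded genes passed in 2 of 11 alternatives and histones in 1, the estimated correlation aside. The gene count was 12 without Nras replicate 3, 5 without compound replicate 3, and 1 without wild-type replicates 1 or 2 or compound replicates 1 or 2, and 6 lists passed without Nras replicate 1 and 1 without Nras replicate 2.

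The compound mutant was compared with Tet2 mutants for what the Nras allele adds to Tet2 loss, and these 6 libraries do not include wild type. Gem rose from 4.19 ± 1.53 to 37.6 ± 9.26 RPKM (SD, n = 3), a log2 difference of 3.19 ± 0.33 (SE, interval 2.47 to 3.91, adjusted p = 0.0259). It lies on chromosome 4 (11704457 to 11714752), and was the 1 gene that rose, with 0 that fell. The G2/M list rose, with 24 of 26 positive and a median of 0.74 (adjusted p = 9.84e-17), and kept its call with an estimated correlation (adjusted p = 0.0432). Adjusted over the list alone 11 members rose, against 0 over all genes. Among them were Top2a (24.7 ± 0.158 to 41.7 ± 3.48 RPKM), Mki67 (75.4 ± 7.86 to 153 ± 19.3), Hmmr (5.50 ± 1.15 to 12.1 ± 2.62) and Nusap1, a spindle protein (5.61 ± 0.595 to 11.5 ± 1.46). The S phase list rose, with 22 of 25 positive and a median of 0.25 (adjusted p = 3.69e-05, and adjusted p = 0.316 with an estimated correlation). Its 1 member that rose adjusted over the list alone (0 over all genes) was Ccne2, from 0.738 ± 0.05 to 2.43 ± 0.475 RPKM. Histones rose, with 19 of 22 positive and a median of 0.46 (adjusted p = 6.85e-05, and adjusted p = 0.479 with an estimated correlation), with 0 members past either adjustment. Hist1h1b stood at 60.5 ± 9.63 against 35.6 ± 4.91 and Hist1h1c at 185 ± 24.7 against 120 ± 11.4. MAPK output did not pass as a list, and Dusp6 (17.1 ± 4.2 to 31.6 ± 5.67) and Spred1, a Ras inhibitor (22.6 ± 0.795 to 28.8 ± 1.82), rose adjusted over the list alone, with 0 over all genes.

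Stem cell genes fell as a list in compound against Tet2 mutants, with 21 of 31 HSC identity members negative and a median of -0.21 (adjusted p = 0.0135, and adjusted p = 0.479 with an estimated correlation). Ifitm1 (34.3 ± 3.87 to 14.2 ± 1.78 RPKM) and Fgd5, an HSC marker (13.3 ± 1.06 to 6.95 ± 1.61), were the 2 members that fell adjusted over the list alone, with 0 over all genes. Hlf, an HSC transcription factor, stood at 47.4 ± 4.34 against 66.9 ± 1.13. STAT5 targets fell, with 11 of 13 negative and a median of -0.79 (adjusted p = 0.00219, and adjusted p = 0.306 with an estimated correlation), with 0 members past either adjustment. Pim2, a survival kinase, stood at 2.66 ± 1.05 against 5.47 ± 0.838 and Cish, a cytokine signaling inhibitor, at 3.48 ± 1.42 against 5.79 ± 1.25. Mitochondrially encoded genes fell, with 13 of 13 negative and a median of -0.62 (adjusted p = 8.87e-05, and adjusted p = 0.509 with an estimated correlation), though 0 passed singly by either adjustment. For mt-Nd5 values were 149 ± 34.0 against 254 ± 45.3 RPKM and for mt-Nd1 79.7 ± 5.30 against 152 ± 24.1. The level of this list was -0.386, -0.471 and 0.029 in compound replicates, which had 2546, 2621 and 1711 genes at 0 reads. In Tet2 replicates it was 0.046, 0.233 and 0.464, with 2512, 1265 and 1312 such genes. Library complexity and uneven depletion of mitochondrial RNA thus stay open for this fall. Interferon response genes (median 0.16, 22 of 32 positive) and antigen presentation genes (0.14, 12 of 15 positive) rose at an adjusted p of 0.0492 each, and had an adjusted p = 0.509 and an adjusted p = 0.479 with an estimated correlation. No member of either passed singly by either adjustment. Ifih1, a sensor of viral RNA, stood at 10.5 ± 1.18 against 7.62 ± 0.843 RPKM, Xaf1 at 5.77 ± 0.521 against 3.10 ± 0.493, and Ciita, the activator of MHC class II genes, at 3.19 ± 1.40 against 1.93 ± 0.294.

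Other genes of that comparison with the smallest p did not pass. Slc22a3 stood at 39.9 ± 7.79 in compound against 20.9 ± 2.63 RPKM in Tet2 mutants, Fut8 at 18.2 ± 2.44 against 38.0 ± 8.42 and Gda at 2.89 ± 1.10 against 11.1 ± 2.14. Fam69b stood at 2.55 ± 0.434 against 7.22 ± 0.0472 and Epb4.1l4b, a cytoskeletal adaptor, at 4.89 ± 0.937 against 11.3 ± 0.413, with adjusted p between 0.302 and 0.356. Xlr4d-ps was at least 10.5-fold lower (adjusted p = 0.292). Unadjusted p was under 0.05 for 844 genes, and groups did not overlap for 12.7% of genes, where chance gives 10%. Gem lost its call with only the 2 groups in the fit (0.0884), the replicate block (0.179), voom (0.0963) and sex as a covariate (0.0869), within a range of 0.0169 to 0.179. It also lost it without wild-type replicate 3 (0.0628), Tet2 replicates 1 (0.102) or 2 (0.115) or compound replicates 1 (0.114) or 2 (0.176). The count of genes was 6 without compound replicate 3, 3 without wild-type replicate 1 or Nras replicate 1, 2 without wild-type replicate 2 or Nras replicate 2, and 0 without wild-type replicate 3, Tet2 replicates 1 or 2 or compound replicate 2. Without compound replicate 3, 5 lists passed and the HSC identity call was lost (0.196). The interferon call was lost with log2(RPKM + 0.5) (0.0526), only the 2 groups in the fit (0.0531), the replicate block (0.0805), voom (0.0533) and sex as a covariate (0.117). It was also lost without compound replicate 3 (0.507), wild-type replicate 2 (0.0545) or Tet2 replicates 2 (0.149) or 3 (0.368). The antigen call was lost with log2(RPKM + 0.5) (0.0622), median-centred libraries (0.05, just above the threshold), quantile normalization (0.17), only the 2 groups in the fit (0.0645), no variance trend (0.0714) and voom (0.108). It was also lost without wild-type replicates 2 (0.0545) or 3 (0.0649), Tet2 replicates 2 (0.204) or 3 (0.319) or compound replicates 1 (0.424) or 3 (0.0742).

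The interaction asked whether the 2 alleles together differ from the sum of each alone. Gm15371, an unprocessed pseudogene on chromosome 1 (88153788 to 88154571), had 0 reads in wild type and in compound mutants but stood at 3.82 ± 2.83 RPKM in Nras mutants and 3.42 ± 2.24 in Tet2 mutants (SD, n = 3). It was thus at least 25.2-fold and 22.5-fold higher in the single mutants than in wild type. 1600002K03Rik stood at 5.88 ± 1.59 RPKM in Nras mutants, 3.35 ± 2.12 in Tet2 mutants and 3.58 ± 0.243 in compound mutants, above the 0 reads of wild type in each. These 2 genes passed, both below the sum of the alleles (adjusted p = 0.0144 each), and 0 passed above it. Mitochondrially encoded genes fell below the sum as a list, with 13 of 13 negative and a median of -0.62 (adjusted p = 0.0299, and adjusted p = 0.987 with an estimated correlation). For mt-Nd4 the values were 49.6 ± 18.4 RPKM in wild type, 54.8 ± 31.6 in Nras, 59.3 ± 14.2 in Tet2 and 27.0 ± 6.90 in compound mutants, and mt-Nd1 stood at 121 ± 53.8, 119 ± 57.9, 152 ± 24.1 and 79.7 ± 5.30. No member passed by either adjustment.

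Neither the G2/M list nor Gem departed from the sum in a way that passed. The interaction was -0.01 for Top2a (interval -0.43 to 0.40) and 0.56 for Gem (-0.46 to 1.59), and the list had a median of 0.13 and a mean of -0.13, opposite in sign (adjusted p = 0.732). Genes with the next smallest p did not pass, with adjusted p between 0.417 and 0.996. Zfp277, a zinc finger protein, stood at 5.90 ± 1.25, 3.39 ± 0.954, 3.46 ± 0.962 and 6.71 ± 1.55 RPKM in wild type, Nras, Tet2 and compound mutants. Fgfr1op2 stood at 14.8 ± 0.154, 13.4 ± 1.01, 12.3 ± 0.179 and 16.9 ± 0.849, and RP24-137F10.1 at 68.6 ± 10.6, 49.5 ± 10.5, 39.6 ± 4.19 and 66.8 ± 11.7. RP24-240P8.1 and RP23-370D2.2 were also above the sum. Rwdd2b stood at 3.67 ± 0.738, 8.28 ± 2.45, 7.93 ± 0.585 and 5.45 ± 0.645. Zfp820 stood at 4.69 ± 1.23, 8.22 ± 0.603, 8.42 ± 0.660 and 4.96 ± 1.68, and AC092711.4, RP24-317M4.6 and RP23-153H17.6 were also below the sum. Unadjusted p was under 0.05 for 523 genes. 1600002K03Rik and Gm15371 lost their calls with log2(RPKM + 0.5) (0.413 and 0.152), quantile normalization (1 and 0.445), the replicate block (0.128 each), voom (0.937 each), and the 2 libraries left out (0.0916 and 0.136). They also lost them without Nras replicates 1 (0.218 and 0.222) or 2 (0.184 each), Tet2 replicate 3 (0.196 each) or compound replicate 2 (0.0629 each), and Gm15371 without Tet2 replicates 1 (0.0848) or 2 (0.0792). The count was 0 genes without each of the first 4 libraries, 1 without Tet2 replicate 2, 4 without Nras replicate 3 or compound replicate 1, and 6 without wild-type replicate 2 or compound replicate 3. The mitochondrial call was lost with no variance trend (0.0671) and without wild-type replicate 1 (0.930), Nras replicate 3 (0.489), Tet2 replicate 3 (0.277) or compound replicates 1 (0.170) or 2 (0.160), each of which gave 0 lists. Then 2 lists passed without wild-type replicate 2.

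Averaging the Nras allele over the Tet2 genotypes compared 6 carriers with 6 other libraries, a comparison added after the data were seen. Gem rose from 5.88 ± 1.12 to 37.7 ± 15.2 RPKM on wild-type Tet2 and from 4.19 ± 1.53 to 37.6 ± 9.26 on Tet2+/- (SD, n = 3), a log2 difference of 2.91 ± 0.23 (SE, interval 2.40 to 3.42, adjusted p = 0.00235). Slc22a3 (chromosome 17, 12418960 to 12507704) rose from 19.0 ± 1.67 to 38.2 ± 2.73 and from 20.9 ± 2.63 to 39.9 ± 7.79 (log2 0.96 ± 0.11, interval 0.72 to 1.21, adjusted p = 0.0263). Top2a (chromosome 11, 98992943 to 99024189) rose from 22.8 ± 2.18 to 39.0 ± 6.44 and from 24.7 ± 0.158 to 41.7 ± 3.48 (log2 0.76 ± 0.09, interval 0.55 to 0.96, adjusted p = 0.0376). Gda (chromosome 19, 21391307 to 21473445) fell from 10.4 ± 2.66 to 2.63 ± 1.14 and from 11.1 ± 2.14 to 2.89 ± 1.10 (log2 -2.01 ± 0.26, interval -2.58 to -1.43, adjusted p = 0.0439). With 1600002K03Rik (adjusted p = 0.00622), which had 0 reads in wild type but not in Tet2 mutants, 4 genes rose and 1 fell. Other genes with small p that did not pass were Robo3, Mki67, Fut8 and Plxdc2 (adjusted p = 0.0565 each), then Csf2rb (0.114) and Epb4.1l4b (0.138). The calls depend on the method. By voom more genes passed, among them Robo3 (0.0129), Mki67 (0.00492), Fut8 (0.00791), Plxdc2 (0.00999) and Epb4.1l4b (0.0194). With quantile normalization only Gem did.

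**Figure D2:**
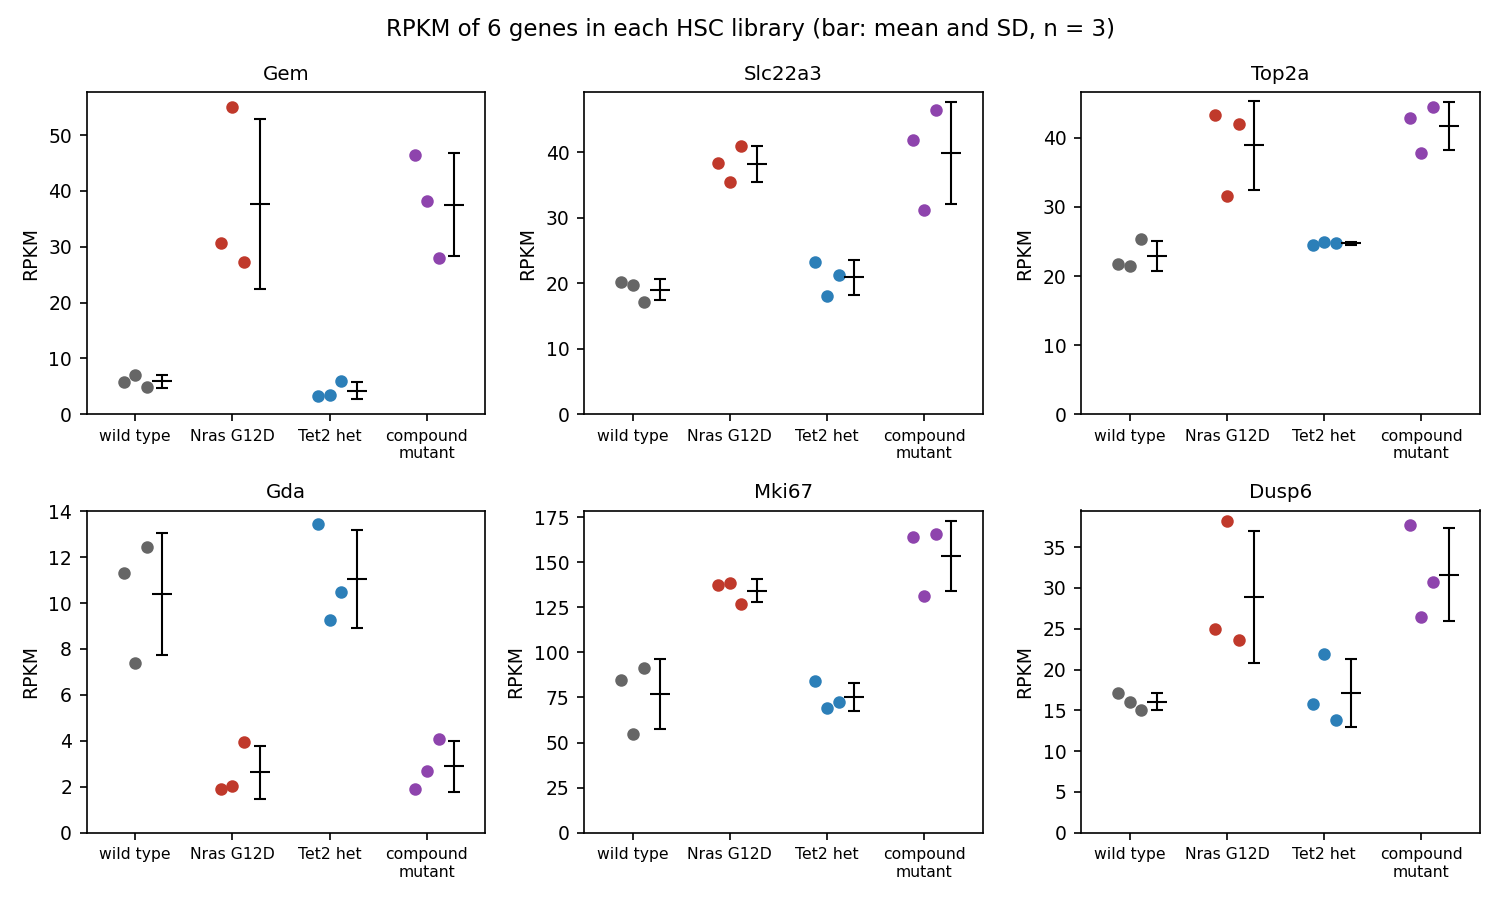
RPKM of single genes in each of the 12 libraries by genotype, with group means and SD (n = 3). Gem has means of 37.7 and 37.6 RPKM in the genotypes with the Nras allele and 5.88 and 4.19 in the others, and Gda 2.63 and 2.89 against 10.4 and 11.1.

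Cell cycle lists rose in carriers of the Nras allele. All but 1 of the 26 G2/M members were positive, with a median log2 difference of 0.69 (adjusted p = 2.93e-19), and the call held with an estimated correlation (adjusted p = 0.0279). Adjusted over the list alone 15 members rose, and 1, Top2a, over all genes. Mki67 (log2 0.93 ± 0.13 SE), Kif11 (0.85 ± 0.12) and Hmmr (0.81 ± 0.15) were among the 15. The S phase list rose, with 25 of 25 positive and a median of 0.24 (adjusted p = 1.34e-07, and adjusted p = 0.208 with an estimated correlation). Ccne2 was its 1 member that rose adjusted over the list alone, with 0 over all genes, and Pola1 (0.40 ± 0.12) and Mcm7, a replication helicase subunit (0.40 ± 0.14), did not pass. Histones rose, with 20 of 22 positive and a median of 0.39 (adjusted p = 1.34e-07, and adjusted p = 0.225 with an estimated correlation), and 8 members rose adjusted over the list alone with 0 over all genes. These included Hist1h1b (0.76 ± 0.15), Hist1h2ab (0.71 ± 0.17), Hist1h1c (0.55 ± 0.14) and Hist1h3b (0.67 ± 0.19). MAPK output rose, with 11 of 16 positive and a median of 0.26 (adjusted p = 0.00455, and adjusted p = 0.225 with an estimated correlation). Its 5 members that rose adjusted over the list alone (0 over all genes) included Dusp6 (0.86 ± 0.16), Ccnd1 (0.82 ± 0.21), Spred1 (0.25 ± 0.07) and Etv5 (1.16 ± 0.31).

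The same 4 lists passed an exact permutation test of each library's list level (the median over members), two-sided and adjusted over 28 lists. The G2/M level was 0.40 ± 0.15 (SD, n = 6) in carriers against -0.32 ± 0.15 in the others on the log2 scale, with 6 of 6 carriers above all non-carriers (exact p = 0.00216, the smallest the test can give, adjusted p = 0.0303). MAPK output stood at 0.17 ± 0.17 against -0.07 ± 0.10, also 6 of 6 (exact p = 0.00216, adjusted p = 0.0303). Its level rose from -0.11 ± 0.15 to 0.27 ± 0.19 on wild-type Tet2 but only from -0.03 ± 0.04 to 0.07 ± 0.07 on Tet2+/- (SD, n = 3). Compound replicates 2 and 3, at 0.026 and 0.033, lay just above wild-type replicate 2 at -0.004, the highest non-carrier. S phase differed by 0.26 and histones by 0.48, each with 5 of 6 carriers above all others (exact p = 0.00433, adjusted p = 0.0303). In a test added after the results were seen, with carrier labels exchanged only within replicate numbers, none of the 4 passed (adjusted p = 0.0519 for G2/M, MAPK output and S phase and 0.0864 for histones, permutation). The smallest p that test can give, 0.00926, was reached by 5 lists, which over 28 lists leaves the 0.0519, so it had little room to pass any.

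**Figure D3:**
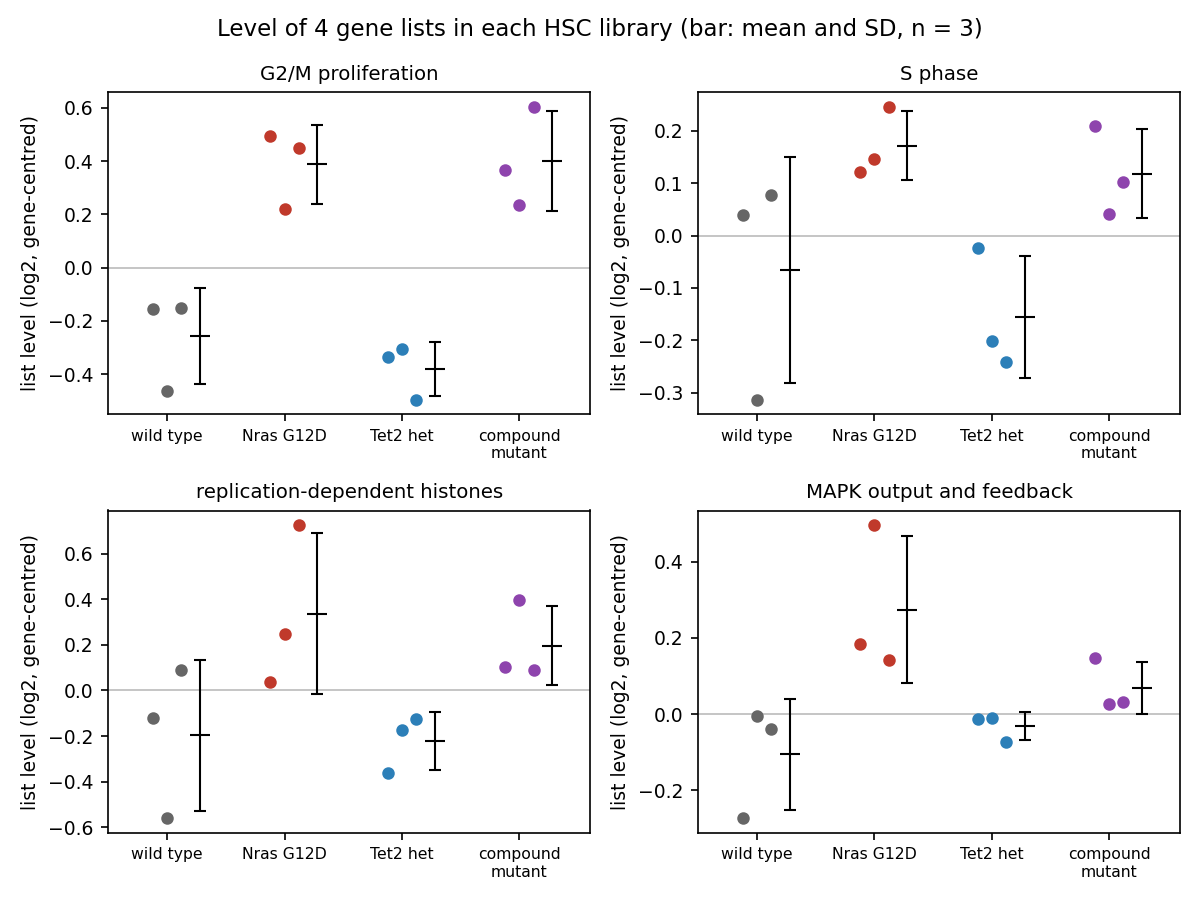
Log2 level of gene lists (median over members, each relative to its mean over all libraries) in each of the 12 libraries, by genotype with group mean and SD (n = 3). The G2/M list stands at 0.39 and 0.40 in Nras and compound mutants and at -0.26 and -0.38 in wild type and Tet2 mutants.

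In carriers the HSC identity list fell, with 21 of 31 negative and a median of -0.15 (adjusted p = 0.0270, and adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone Ifitm1 (log2 -1.11 ± 0.22 SE), Fgd5 (-0.82 ± 0.17) and Hlf (-0.37 ± 0.10) fell and Gata2, a stem cell transcription factor (0.38 ± 0.10), rose, 3 and 1 members, with 0 over all genes. STAT5 targets fell, with 8 of 13 negative and a median of -0.24 (adjusted p = 0.0337, and adjusted p = 0.278 with an estimated correlation), and Socs2, a cytokine signaling inhibitor, was the 1 member that fell adjusted over the list alone, with 0 over all genes. Socs2 stood at 0.277 ± 0.182 and 0.442 ± 0.146 RPKM in the carrier genotypes against 1.58 ± 0.227 and 1.29 ± 0.517. The level of the STAT5 list was 0.13 ± 0.28 in Nras mutants against 0.22 ± 0.51 in wild type (log2, SD, n = 3). On Tet2+/- it was -0.27 ± 0.27 in compound against 0.51 ± 0.20 in Tet2 mutants. The list fell mainly on that background, although its interaction did not pass. Csf2rb fell adjusted over the cytokine receptor list alone (log2 -0.90 ± 0.15, 0.00227). Mitochondrially encoded genes fell, with 12 of 13 negative and a median of -0.41 (adjusted p = 0.0105, and adjusted p = 0.488 with an estimated correlation), and 0 members passed. The median was -0.62 on Tet2+/- and 0.00 on wild-type Tet2. The interaction, which tests that difference, had an adjusted p of 0.0299 (camera). It was 0.987 with an estimated correlation and 0.930 without wild-type replicate 1, so the fall cannot be placed on 1 background. The 0.00 includes wild-type replicate 1 and Nras replicate 2, which had the lowest list levels (-0.731 and -0.649) and the most genes at 0 reads. Uneven depletion of mitochondrial RNA stays open here too. Lists of immune genes also rose, interferon response by a median of 0.25 with 25 of 32 positive (adjusted p = 0.00647, and adjusted p = 0.278 with an estimated correlation). Antigen presentation rose by 0.09 with 14 of 15 positive (adjusted p = 0.0270, and adjusted p = 0.278 with an estimated correlation). No member of either passed. Ifih1 stood at log2 0.34 ± 0.11 and Usp18, which removes ISG15, at 0.51 ± 0.23. Usp18 stood at 4.884 ± 0.3272 RPKM in wild type and 11.07 ± 1.135 in Nras mutants. On Tet2+/- it was not higher with the Nras allele (10.14 ± 3.604 in Tet2 and 9.129 ± 3.56 in compound mutants). Ciita stood at 0.70 ± 0.28 and Psmb9, a proteasome subunit, at 0.30 ± 0.13. Megakaryocyte genes rose, with 15 of 20 positive and a median of 0.50 (adjusted p = 0.0291, and adjusted p = 0.336 with an estimated correlation), and 0 members passed. Pf4, a platelet chemokine, stood at 10.2 ± 6.4 and 8.49 ± 1.86 RPKM in carriers against 2.38 ± 0.466 and 1.82 ± 1.58, and Selp, P-selectin, at 13.7 ± 1.05 and 11.9 ± 4.51 against 7.69 ± 4.37 and 5.08 ± 3.10. None of these 6 lists passed the exact permutation test (HSC identity, adjusted p = 0.162).

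In carriers of the Nras allele unadjusted p was under 0.05 for 1121 genes, and 131 genes, or 0.8%, did not overlap between 6 and 6 libraries, where chance gives 0.216%. Gem and the G2/M list held in all alternatives and with any library left out, with adjusted p up to 0.0256 for Gem. Slc22a3 lost its call with quantile normalization (0.0524), no variance trend (0.0813), the 2 libraries left out (0.155) and without wild-type replicates 1 (0.0656) or 3 (0.0574), Nras replicates 1 (0.0962) or 2 (0.0638), Tet2 replicates 2 (0.0992) or 3 (0.12) or compound replicate 1 (0.0959). Top2a lost it with quantile normalization (0.0864), no variance trend (0.113), sex as a covariate (0.0602) and without any library other than Nras replicates 2 or 3 (0.0552 to 0.144). 1600002K03Rik lost it with log2(RPKM + 0.5) (0.0643), quantile normalization (0.258) and voom (0.156). Gda lost it in 5 alternatives (0.0519 to 0.205) and without any library other than wild-type replicate 2, Nras replicate 3 or compound replicate 3 (0.0805 to 0.160). The gene count was 17 without Nras replicate 3, 12 without wild-type replicate 2, 3 without wild-type replicate 1, Nras replicates 1 or 2 or compound replicates 1 or 2, and 2 without wild-type replicate 3 or Tet2 replicates 2 or 3. The call of HSC identity was lost without wild-type replicates 1 (0.0842) or 2 (0.102), Nras replicate 3 (0.214) or compound replicate 3 (0.114). That of STAT5 targets was lost without wild-type replicates 2 (0.218) or 3 (0.0720), Nras replicates 1 (0.0536) or 3 (0.113), Tet2 replicate 3 (0.0506) or compound replicate 2 (0.123), and that of interferon with the 2 libraries left out (0.0712) or without Nras replicate 2 (0.0766) or compound replicate 3 (0.0506). Antigen presentation lost its call with quantile normalization (0.0716), the 2 libraries left out (0.0545) or without wild-type replicate 2 (0.165), Nras replicate 2 (0.109), Tet2 replicates 2 (0.0638) or 3 (0.0747) or compound replicate 1 (0.123). Megakaryocyte genes lost it with sex as a covariate (0.0561), the 2 libraries left out (0.0712) or without wild-type replicate 1 (0.108), Nras replicate 3 (0.187) or compound replicate 1 (0.0967). Mitochondrial genes lost it without wild-type replicates 2 (0.105) or 3 (0.0985) or Nras replicate 2 (0.0688), and 6 lists passed without wild-type replicate 2.

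Averaging the Tet2 allele over the Nras genotypes, also added after the data were seen, compared 6 Tet2+/- libraries with 6 others. Sertad1 stood at 3.23 ± 0.595 and 2.83 ± 0.982 RPKM in Tet2 and compound mutants against 7.37 ± 0.441 and 5.53 ± 1.34 in wild type and Nras mutants (SD, n = 3). Nsmce2, a SUMO ligase of DNA repair, stood at 8.31 ± 1.47 and 6.64 ± 2.15 against 3.63 ± 1.23 and 3.73 ± 0.750. Zufsp, a deubiquitinase, stood at 36.7 ± 6.13 and 34.3 ± 4.43 against 24.7 ± 2.44 and 22.0 ± 5.50. Lsm4, an RNA-binding protein of the spliceosome, stood at 14.6 ± 1.10 and 18.6 ± 2.65 against 8.39 ± 2.89 and 9.74 ± 4.14. Tnrc6a and mmu-mir-721 were also higher. Napsa, an aspartic protease, stood at 11.3 ± 1.30 and 9.74 ± 1.91 against 15.9 ± 3.56 and 14.4 ± 0.496, and Gbp9, Ptp4a3 and Cnbp were also lower. These genes had small p, and none of them passed (adjusted p = 0.963). By limma 0 genes changed, with 589 at an unadjusted p under 0.05 and 0 by voom, and 20 genes, or 0.1%, did not overlap, where chance gives 0.216%.

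Small shifts of lists passed with the Tet2 allele. Genes of stroma and endothelium rose, with 6 of 7 positive and a median log2 difference of 0.33 (adjusted p = 0.0287, and adjusted p = 0.384 with an estimated correlation). Col4a1, a basement membrane collagen, stood at 19.6 ± 2.97 and 13.2 ± 1.33 RPKM against 15.2 ± 2.35 and 11.1 ± 1.76. The unfolded protein and integrated stress response list fell, with 16 of 18 negative and a median of -0.18 (adjusted p = 0.0240, and adjusted p = 0.643 with an estimated correlation), with Herpud1 at log2 -0.41 ± 0.24 (SE). Antigen presentation fell by a median of 0.11 with 11 of 15 negative (adjusted p = 0.0240, and adjusted p = 0.384 with an estimated correlation), with H2-Ab1 at log2 -0.68 ± 0.25. Glycolysis (median -0.09, 12 of 16 negative) and S phase (-0.05, 19 of 25 negative) fell at an adjusted p of 0.0287 each, and had an adjusted p = 0.384 and an adjusted p = 0.644 with an estimated correlation. Gpi1 stood at log2 -0.19 ± 0.06 and Cdc45, a replication factor, at -0.49 ± 0.17. Cytosolic ribosomal proteins fell, with 34 of 49 negative and a median of -0.08 (adjusted p = 0.0287, and adjusted p = 0.913 with an estimated correlation), with Rps7 at -0.26 ± 0.10. No member of these lists passed adjusted over the list alone or over all genes, and none of the lists passed the exact permutation test (smallest adjusted p = 0.566). The DNA methylation machinery had a median of -0.02 (adjusted p = 0.870). All 6 calls were lost with quantile normalization (0.149 to 0.609) and with the 2 libraries left out (0.331 to 0.538), and each with 6 to 8 of the 12 libraries left out in turn. With the replicate block S phase (0.0512), stroma (0.0673) and glycolysis (0.0574) did not pass, and with no variance trend neither glycolysis nor ribosomal proteins (0.058 each). Sex as a covariate ended the calls of stroma (0.0722) and ribosomal proteins (0.247), no minimum on RPKM that of stroma (0.0528) and voom that of glycolysis (0.0565). The number of lists was 0 without wild-type replicate 1, Nras replicate 2 or Tet2 replicate 3, 1 without wild-type replicate 3, Nras replicate 3 or compound replicate 3, and 2 without Tet2 replicate 2 or compound replicate 1. The gene count was 7 without wild-type replicate 2, 5 without Nras replicate 3, 2 without compound replicate 3 and 1 without compound replicates 1 or 2.

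The remaining lists did not pass in carriers of the Nras allele. Their median log2 differences were -0.06 for quiescence (adjusted p = 0.622), -0.55 for immediate early genes with 15 of 16 negative (0.0855), -0.01 for cytokine receptors (0.579), -0.02 for NF-kB and inflammation (0.948) and 0.13 for the DNA methylation machinery (0.201). Ras pathway components stood at 0.09 (0.157), the Hox list at -0.07 (0.157), oxidative phosphorylation at 0.00 (0.854), cholesterol synthesis at -0.09 (0.201) and MYC targets with ribosome biogenesis at -0.01 (0.673). The p53 list had a median of -0.08 and a mean of 0.04, opposite in sign (0.608). Glycolysis stood at -0.08 (0.189), the unfolded protein and stress response at -0.14 (0.0525), ribosomal proteins at -0.02 (0.525) and stroma and endothelium at -0.35 (0.189). Immediate early genes passed with quantile normalization (0.0374), the replicate block (5.88e-05), quality weights (8.85e-05), sex as a covariate (0.000138) and the 2 libraries left out (0.000206), within a range of 5.88e-05 to 0.683. They also passed without wild-type replicates 1 (0.0443) or 3 (0.0495), Nras replicate 2 (0.000668), Tet2 replicate 1 (0.00443) or compound replicate 2 (0.00142). The unfolded protein list passed with log2(RPKM + 0.5) (0.0487), quantile normalization (0.0334), the replicate block (0.0178), voom (0.0369), sex as a covariate (0.00741) and the 2 libraries left out (0.0234), within a range of 0.00741 to 0.347. It also passed without Nras replicate 2 (0.0124), Tet2 replicate 3 (0.00312) or compound replicate 2 (0.0407). Of progenitor lists, lympho-primed genes stood at 0.11 (0.218), granulocyte-monocyte progenitors at -0.22 (0.145) and erythroid genes at 0.13 (0.431).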

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

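Of the tests in this part, those of library complexity, sex, other lineages (within replicate numbers too), the depth behind 1600002K03Rik and mitochondrial RNA depletion were chosen only after the result was seen.

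The G2/M proliferation list was higher in the 6 carriers of the Nras allele, with Top2a, Mki67 and Kif11 the members of smallest p. Library complexity as the whole cause was excluded: with the number of genes at 0 reads as a covariate the carrier difference in list level was 0.71 (SE 0.09, log2), and genes at 0 reads averaged 2259 ± 767 (SD, n = 6) in carriers against 1996 ± 1059 (exact p = 0.63, permutation). Sex as the whole cause was excluded in the same way, with a difference of 0.72 (SE 0.09) once sex was a covariate. Dividing cells of other lineages stay open, although the lineage-negative gate should remove mature ones: of 4 lineage lists the smallest exact p between carriers and others, without regard to replicate number, was 0.0736 (megakaryocytes, 0.36 higher), with erythroid genes 0.31 and lympho-primed genes 0.08 higher and granulocyte-monocyte progenitor genes at -0.16 (exact p = 0.037 within replicate numbers, adjusted p = 0.13), and of abundant members Itga2b stood at 17.2 and 14.5 RPKM in carriers against 11.1 and 10, and Hbb-bt, a hemoglobin, at 9.18 and 2.5 against 10.6 and 3.65. A candidate explanation is therefore that stem cells with NrasG12D divide more often, or that the gate held more cycling progenitors, which bulk RNA does not tell apart and cell cycle staining or RNA of single gated cells would.

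1600002K03Rik was set apart by the test of the interaction, with a fitted log2 value of -8.47 that depends on the prior count and is no bound. It had 0 reads in the 3 wild-type libraries and 21 to 149 in the other 9. Sequencing depth alone was excluded as the cause, since at 1.21 RPKM, the lowest level elsewhere, at least 16.4 reads were expected in each wild-type library. This covers counting error only, because reads are not independent molecules, so too few molecules in the wild-type libraries were not excluded. Drop-out of single genes from libraries of few cells remains open: 40 of the 219 other sets of 3 libraries (18.3%) had at least 1 gene at 0 reads in those 3 and at 1 RPKM or more in the other 9, up to 6 such genes, where the wild-type set had 1. An effect shared by both alleles could not be separated from such drop-out, and no biological explanation was tested.

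Mitochondrially encoded genes were below the sum of the alleles in the compound mutant, with a median interaction of -0.62 (log2) and 13 of 13 members negative. Uneven depletion of mitochondrial RNA, which the library preparation removed, stays open as a possible explanation. The 2 mitochondrial ribosomal RNAs, targets of the same depletion, had an interaction of -0.18 (SE 0.32), which lies within 2 SE of 0 and of the list's median. The list level was lowest in wild-type replicate 1 (-0.731) and Nras replicate 2 (-0.649), with 3824 and 3268 genes at 0 reads. It was highest in Nras replicate 3 (0.661), with 1073. Compound replicates 1 and 2, with 2546 and 2621, stood at -0.386 and -0.471. Library complexity was not tested as a cause of this result.

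Gm15371 was also set apart by the test of the interaction, with 0 reads in wild type and compound mutants and a fitted log2 value of -16.18 that depends on the prior count and is no bound. Chance was not excluded for these results of the interaction, where 29 of 100 splits of the libraries gave 2 or more genes and 90 of 100 gave 1 or more lists.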

How the results depend on the processing

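Voom on recovered reads, sex as a covariate and the fit without the 2 libraries with most genes at 0 reads were chosen only after the results were seen. In each list of 8 numbers here the order is Nras, Tet2 and compound against wild type, compound against Nras, compound against Tet2, the interaction, the Nras allele averaged and the Tet2 allele averaged. For the single genes named by their own p or fold, Nras and Tet2 aside, 1825 values under the alternatives kept their direction and side of the threshold, 40 newly passed, 80 no longer passed and 0 reversed. Genes passing were 1, 1, 1, 0, 1, 2, 5 and 0. With log2(RPKM + 0.5) they were 3, 0, 0 in the first 3 comparisons and 0 in the interaction. With quantile normalization they were 0, 0, 0 and 0 in these, and 1 for the Nras allele. With only the 2 groups in the fit they were 0, 0, 0, 2 and 4 in the first 5. With no variance trend they were 3, 2, 3, 3 and 3 in the first 5 and 1 for the Tet2 allele. The replicate block gave 0 for compound against Tet2 and 0 for the interaction, median-centred libraries 8 and quality weights 11 for the Nras allele. Voom gave 0 in the first 6 comparisons and 20 for the Nras allele, and the sex covariate 0 for compound against Tet2. Without the 2 libraries, 3, 2, 2, 1 and 8 passed in the first 5. With each library left out in turn, counts ran 1 to 18, 1 to 20, 1 to 17, 0 to 12, 0 to 6, 0 to 6, 2 to 17 and 0 to 7, highest without wild-type replicate 2 or Nras replicate 3 except for compound against Tet2 and the interaction, highest without compound replicate 3 (6 each, and 6 without wild-type replicate 2 in the interaction).

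Lists passing were 4, 0, 4, 0, 8, 1, 10 and 6. With an estimated inter-gene correlation 0, 0, 0, 0, 1, 0, 1 and 0 passed. Quality weights gave 7 for Nras and 8 for compound against wild type, and 2 for compound against Nras. For compound against wild type 8 passed with no minimum on RPKM, 8 with the replicate block and 8 with the sex covariate. For Tet2 against wild type 1 passed with quantile normalization, 3 with the replicate block, 1 with voom and 4 with the sex covariate. Without the 2 libraries 7 passed for compound against wild type, 1 for compound against Nras, 2 for the interaction and 1 for the Tet2 allele. The interaction had 0 with no variance trend, and the Tet2 allele 0 with quantile normalization and 3 with the replicate block. With each library left out, counts ran 2 to 8, 0 to 6, 3 to 8, 0 to 6, 5 to 11, 0 to 2, 6 to 11 and 0 to 8. Lists that did not pass were called in 3 or more alternatives, the estimated correlation aside, as follows. Of 11 alternatives these were 3, 4 and 3 for immediate early genes in Nras against wild type, compound against wild type and compound against Tet2, and 3 for mitochondrial genes in Tet2 against wild type. For compound against wild type they were 5 for S phase, 5 for STAT5 targets, 4 for ribosomal proteins and 4 for mitochondrial genes. For the Nras allele they were 5 of 10 for immediate early genes and 6 of 10 for the unfolded protein list. The cause of these changes was not tested.

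The 2 targeted genes changed direction in some settings. Nras differed from wild type by -0.06 to 0.16 in Nras mutants and 0.07 to 0.29 in compound mutants with each library left out, and by -0.08 to 0.17 between compound and Tet2 mutants. Tet2 differed from wild type by -0.16 to 0.02 in Tet2 mutants and -0.1 to 0.07 in compound mutants, and by -0.3 to -0.03 between compound and Nras mutants. The Tet2 difference of 0 between compound and wild type turned to -0.01 with median-centred libraries, -0.02 with quality weights and 0 (just below it) without the 2 libraries. Library medians shifted comparisons by at most 0.034 (log2). The main fit did not pair libraries by replicate number, and the labels do not say what a number marks. Of 18 pairs with the same number 2 correlated above 0.1, from -0.125 to 0.136, though 8 of 12 libraries correlated best with 1 of their own number. That cut over all genes cannot exclude that libraries of a number belong together. Each number holds 1 library of each genotype, and immediate early levels separated the numbers in all 4 genotypes. The main fit leaves differences between numbers in its spread, while the replicate block removes them. Of 224 list medians, 1 changed when genes at 0 reads in a group were set at their bound, granulocyte-monocyte progenitors in the interaction from 0.07 to -0.24. On simulated data of this size 10.2%, 49.8% and 72% of genes changed by a log2 of 1, 2 and 4 were recovered. False calls over 3 draws were 5, 14 and 15. The simulation drew normal values for each gene independently, without replicate numbers, and changed 200 genes per draw. These shares therefore need not hold for the real libraries.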

Other observations

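The tests of each allele's effect between backgrounds, the marker values, the permutation within replicate numbers and the 2 averaged comparisons, with their counts over other splits, were chosen only after the results were seen.

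RNA of the markers of the sorting gate was read from the same libraries. Kit stood at 66.7 ± 1.79, 73.7 ± 10.7, 76.0 ± 1.39 and 81.6 ± 4.80 RPKM in wild type, Nras, Tet2 and compound mutants (SD, n = 3), and Slamf1, which encodes CD150, at 7.99 ± 3.05, 6.26 ± 1.18, 8.02 ± 1.44 and 5.19 ± 1.77. Cd48 had 0 reads in wild type and at most 1.28 RPKM in any library. Ly6a, which encodes Sca1, stood at 3.71 ± 1.39, 6.96 ± 1.41, 4.14 ± 0.717 and 5.89 ± 1.65. Procr, the EPCR antigen of stem cells, stood at 15.5 ± 2.56, 13.1 ± 4.46, 14.8 ± 4.30 and 12.2 ± 5.83. Flt3, higher in multipotent progenitors, stood at 8.20 ± 3.39, 8.62 ± 0.958, 10.0 ± 3.08 and 9.64 ± 3.48, and Cd34 at 22.3 ± 2.87, 20 ± 2.23, 23.6 ± 1.30 and 23.3 ± 2.05.

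Lists of mature cells had fewer than 5 members above the minimum and were not tested as lists, and none of these members passed as single genes. Of mature granulocyte genes 3 of 16 were above it, with Lyz2, lysozyme, at 90.9 ± 7.79, 95.5 ± 17.9, 98.3 ± 6.78 and 95.8 ± 9.65 RPKM in the 4 genotypes (SD, n = 3), S100a9 and Itgam. Of monocyte and macrophage genes there were 4 of 16 (Cd68, Hmox1, Axl and Spic), with Axl, a receptor kinase, at 1.04 ± 0.776, 2.85 ± 0.180, 1.83 ± 0.480 and 2.71 ± 0.755. B lineage genes were 2 of 17, Cd79b at 4.91 ± 1, 6.47 ± 1.56, 3.64 ± 1.37 and 3.48 ± 0.666 and Cd37 at 7.78 ± 0.591, 9.02 ± 2.30, 7.09 ± 1.05 and 11.1 ± 1.26. T and NK genes were 4 of 20 (Cd4, Lck, Cd247 and Nkg7), with Nkg7, a granule protein, at 1.14 ± 1.16, 6.80 ± 5.95, 1.63 ± 1.88 and 5.40 ± 3.09. Of mast cell, basophil and eosinophil genes there were 2 of 14, Cpa3 with 0 reads in wild type and Prg2, an eosinophil granule protein, at 20.9 ± 30.9 in compound mutants and up to 56.6 in 1 library.

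Immediate early genes differed between replicate numbers in all 4 genotypes, with list levels (log2) of -1.791 to -0.572 in the libraries numbered 1, 1.558 to 1.902 in those numbered 2 and -0.735 to 0.342 in those numbered 3. Mitochondrial ribosomal RNA took 4.76 to 5.47%, 5.42 to 5.95% and 5.90 to 6.57% of reads in the same order. Within each number both carriers of the Nras allele had lower immediate early levels than both other libraries (difference -0.67, exact permutation p within numbers = 0.00926, the smallest it can give, adjusted p = 0.0519 over 28 lists), where the exact p without regard to number was 0.42. HSC identity, G2/M, S phase and MAPK output gave the same p within numbers. With 5 lists at the smallest p, 0.0519 is what adjustment over 28 lists leaves, so the test had little room to pass any list and does not count against them. The libraries numbered 1 were all male and those numbered 2 all female, so sex and number cannot be told apart between them. The labels do not say whether a number marks a shared day, and the cause was not tested.

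Across 15478 genes, which are not independent replicates, the Nras effect on wild-type Tet2 and on Tet2+/- correlated with Pearson's r = 0.048 and Spearman's rho = 0.10, and 36 of 100 splits gave a correlation as large (permutation p = 0.36). With log2(RPKM + 0.5) r was 0.066, with 8 of 100 splits as large (permutation p = 0.08). For the Tet2 effect on the 2 Nras backgrounds r was 0.009 and rho 0.025 (82 of 100 splits, permutation p = 0.82).

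Other splits of the libraries were counted for each number of genes and lists. For 3 against 3 there are 10 splits, too few for a share under 0.05. The real number of genes and the highest of the other splits were 1 and 13 for Nras, 1 and 7 for Tet2 and 1 and 6 for compound against wild type, 0 and 9 for compound against Nras and 1 and 3 for compound against Tet2. For lists they were 4 and 10, 0 and 8, 4 and 7, 0 and 4, and 8 and 6. Splits that reached the real number, in the same order and with the real one counted, were 6, 6, 6, 10 and 5 for genes and 6, 10, 4, 10 and 1 for lists. Splits with 13, 7 and 6 genes lay several times above the real 1, and 1 split had 9 where the real one gave 0. These could come from a structure of the samples apart from genotype or from drop-out of single genes, which were not told apart. In the split with 13 genes, wild-type replicates 1 and 3 and Nras replicate 2 formed 1 side. For that set of 3 libraries, 6 genes had 0 reads in those 3 and 1 RPKM or more in the other 9. The splits with 7 and 9 genes parted libraries with many genes at 0 reads from those with few. For 7 these were 2062 to 3824 against 1000 to 1312, and for 9 they were 2546 to 3268 against 1073 to 2335. The splits with 13 and 6 genes did so only in part, and the source was not tested. The splits with 13, 7 and 6 genes share the wild-type libraries and are not independent, and each is the highest of 9 other splits. For the interaction, 29 of 100 splits gave as many genes (2, highest other 13) and 90 as many lists (1, highest other 10), so chance was not excluded. For the Nras allele averaged, 7 of 100 gave as many genes (5, highest other 12), so chance was not excluded. For lists, 1 of 100, the real one, gave as many (10, highest other 9). That is a margin of 1 list, over splits made without regard to replicate number, in a comparison added after the data were seen. It is too narrow to exclude chance. The number of lists, 10, fell to 6 without wild-type replicate 2 and to 1 with an estimated correlation. For the Tet2 allele averaged, 100 of 100 gave as many genes (0, highest other 13) and 25 as many lists (6, highest other 10), so chance was not excluded.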
